A study of Mus musculus with 2 samples.

How the data were processed

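Cells washed from the peritoneal cavity of unmanipulated C57BL/6J mice aged 19 weeks were sorted for CD11b and against SiglecF, CD19, CD3 and Ly6G, and made into 10x Genomics droplet libraries. There was 1 library from females and 1 from males, so sex and library could not be separated, and the labels did not say how many mice each held. The deposited files held counts, namely UMI counts (unique molecular identifiers, 1 per captured transcript) for 27998 genes in each cell barcode, with no normalization. The submitters' processing notes name Cell Ranger 2.1.1 and the mouse build mm10. No barcode in either file had fewer than 2285 UMIs, so empty droplets had been left out before deposit and free RNA could not be measured in them.

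Cells were kept with at least 500 genes and at most 10% mitochondrial UMIs, which removed 14 female and 18 male cells, all for mitochondrial UMIs. Scrublet, as run in scanpy 1.11.5, then called 1 female and 5 male doublets, 0.0864% of 6943 barcodes, a share too low for this loading. Doublet removal was therefore treated as not having worked, and leaving out cells over 2 times their library's median UMIs was added as an alternative. Counts were scaled to 10000 per cell and log-transformed, and both libraries were clustered together on 2000 variable genes, without the sex check genes. Clustering used 30 components, 15 neighbours and Leiden resolution 1 (leidenalg 0.10.2, igraph 0.11.9, Python 3.11.15).

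Clusters were named from marker lists. A cluster was called LPM-like (large peritoneal macrophage) when the median level of its LPM markers was at least 0.5 of that in all cells and fewer than 3 of its 10 leading genes were markers of another class. It was given another class when LPM markers were below 33.3% of that level and at least 3 markers of the other class were over 2-fold higher than in the rest. Any other cluster stayed unnamed. The thresholds of this naming rule were set after the data had been seen, and were loosened once after the cDC2-like cluster (type 2 conventional dendritic cell) had lost its name under several alternatives.

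For each class the UMIs of its cells were summed per library and expressed as counts-per-million (CPM) of the class total. Levels have exact Poisson 95% intervals, ratios exact conditional binomial intervals, and shares of cells exact binomial (Clopper-Pearson) intervals. Any count below 3, including 0, entered a ratio as 3 counts, which makes the ratio a bound. Intervals and floors cover counting error only, and with 1 library per sex no test of a difference was possible. The gene lists, the lists of cell markers, the subset panel and the rule for naming genes were fixed before the data were examined, but how the naming of clusters used the markers was not. The rule for genes took, among genes at 20 CPM or more in the higher library, the 12 with the largest ratio each way. It added the sex check genes, the subset panel, and 2 to 4 members of each list at 5 CPM or more with the largest ratios. Each list was described by its median log2 ratio, the number of members at least 1.5-fold apart, and the percentile of its median among 10000 random lists of the same size matched on expression.

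Shares of LPM-like cells with a UMI of a gene were taken after thinning each cell at random to 5817 UMIs, the 10th percentile of the LPM-like cells of the shallower library, with shallower cells left out. Background shares came from cDC2-like cells of the same library, since too few lymphocyte-like cells were found. A cell was counted as cycling with UMIs of at least 3 of the 25 genes of the G2M list. Alternatives covered scaling (TMM factors from edgeR 4.0.16 in R 4.3.3, median of ratios, a total without mitochondrial, ribosomal protein and sex check genes, and the mean over cells), the expression floor, the choice of cells, thinning, doublets, the cell filter and the clustering. Gene positions were taken by symbol from GENCODE M21, which uses the same assembly as mm10, and 114 of the 115 named symbols matched once. Other tools were numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

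The calculation of the ratios was checked on simulated data with known folds. The counts were drawn as Poisson around 1 pooled profile, which is the model that the intervals assume. They held no variation between cells, mice or libraries, so the check says nothing on how often such variation gives a 2-fold gene. For 4049 genes simulated without a difference, 95.3% of the intervals held the true ratio and 0 genes came out at least 2-fold apart. Of 50 genes simulated at each fold, 0% of those at 1.5-fold, 58.0% of those at 2-fold and 100% of those at 3-fold and at 4-fold came out at least 2-fold apart in the right direction. Thinning moved the share of any of 129 simulated genes by at most 2.38%.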

Results

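The data were single-cell transcriptomes of peritoneal myeloid cells, a population made up mostly of resident macrophages, from female and male mice. The female library held 4351 cell barcodes, of which 4336 cells with 43744672 UMIs in all were kept. The male library held 2592 barcodes, of which 2569 cells with 29657340 UMIs in all were kept. Kept cells had a median of 9767.5 UMIs and 2341.5 genes in the female library and of 10885 UMIs and 2595 genes in the male library. The median mitochondrial share was 2.27% in female and 2.59% in male cells. There were no replicates: each sex was 1 library, and every comparison below is between these 2 libraries.

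The sex check genes separated the libraries as labelled. Xist, the RNA that coats the inactive X chromosome, was at 414.6 CPM in female cells (95% interval 408.6 to 420.6) and had 0 UMIs in male cells, where 3 counts stand for 0.101 CPM and the exact upper limit was 0.124 CPM. Its antisense gene Tsix was at 4.39 CPM in female and 0 UMIs in male cells. The Y-linked genes Eif2s3y, Ddx3y, Kdm5d and Uty were at 48.3, 39.8, 10.5 and 9.71 CPM in male cells. All 4 had 0 UMIs in female cells, where 3 counts stand for 0.0686 CPM and the exact upper limit was 0.0843 CPM.

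The question of the first comparison was which cell classes the sort held in each sex. LPM-like cells, the Gata6-expressing macrophages that fill the resting peritoneal cavity, made up 83.5% of the 4336 female cells (82.4 to 84.6) and 86.3% of the 2569 male cells (84.9 to 87.6). MHCII macrophage-like cells, the class with markers of small, monocyte-derived peritoneal macrophages such as Ccr2 and H2-Aa, made up 2.05% of female (1.65 to 2.52) and 2.61% of male cells (2.03 to 3.30). The cDC2-like cells made up 1.38% of female (1.06 to 1.78) and 2.26% of male cells (1.72 to 2.91). A further 565 female cells (13.03%, 12.04 to 14.07) and 228 male cells (8.88%, 7.80 to 10.0) lay in clusters that met no naming rule. The order of the LPM-like shares turned in 4 of 8 alternatives. The female and male shares were 89.8% and 87.3% when the clusters were made without the 198 genes that differed 2-fold between the libraries, 89.0% and 85.5% with at least 1000 genes and at most 5% mitochondrial UMIs, 91.1% and 88.8% at resolution 2, and 91.9% and 88.1% without cells over 2 times the median UMIs. No class other than LPM-like reached 100 cells in both libraries, so the rule for naming genes was applied to no other class.

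**Figure D1:**
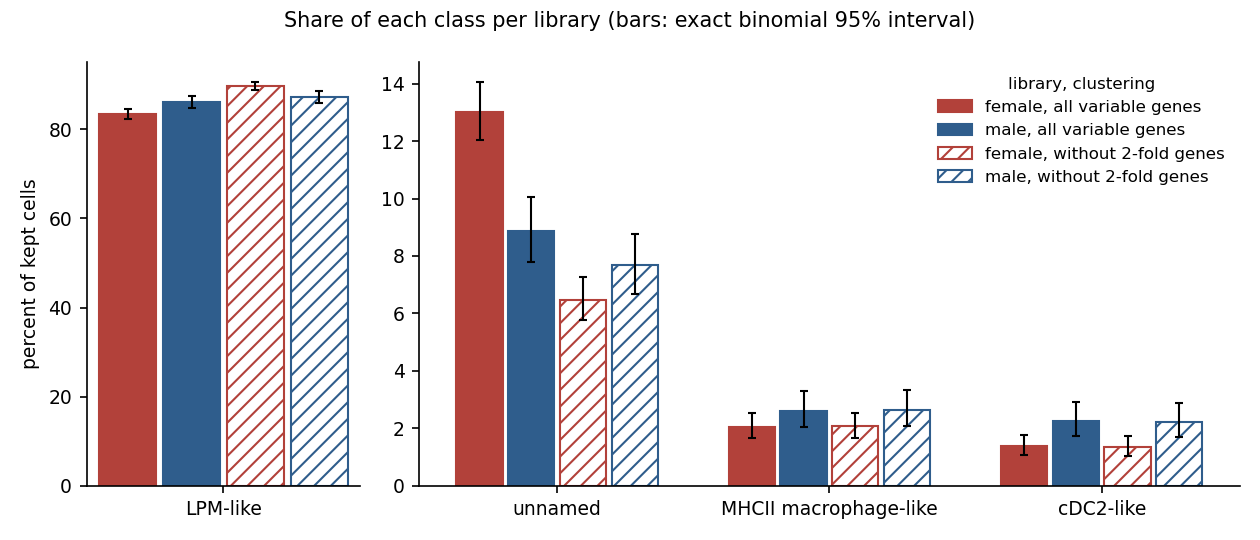
Percent of kept cells in each class for the female and the male library, from the main clustering (filled) and from clustering without genes that differ 2-fold between the libraries (hatched), with exact binomial 95% intervals as bars. The LPM-like share was 83.5% in the female and 86.3% in the male library in the main clustering, and 89.8% and 87.3% without those genes.

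The main comparison asked how LPM-like cells of females and males differed. In female LPM-like cells Cxcl13, a chemokine that attracts B cells, was 6.08-fold higher at 7724 against 1269 CPM (log2 2.61, 2.59 to 2.62), and Saa3, an acute-phase serum amyloid, was 3.72-fold higher at 15883 against 4265 CPM (log2 1.90, 1.89 to 1.91). Apoc1, which encodes an apolipoprotein, was 5.11-fold higher (log2 2.35, 2.27 to 2.43), and Cd209b, a C-type lectin that binds microbial sugars, was 3.46-fold higher (log2 1.79, 1.63 to 1.95). Complement C3 and Cfb, both of the alternative pathway, were 2.93-fold and 2.85-fold higher in the female library. Male LPM-like cells held more Chil3, a chitinase-like protein, at 28.1 against 2.06 CPM (13.7-fold, log2 -3.77, -4.14 to -3.42), more Arg1, which encodes arginase, at 439.8 against 87.3 CPM (5.04-fold, log2 -2.33, -2.39 to -2.27), and more RNA of cell-cycle genes. The Chil3 ratio moved by over 1.5 times in 7 of 20 alternatives, to log2 -2.69 (6.44-fold) with all cells kept and -2.83 in cells chosen by single UMIs. Clusters were also made without 2-fold genes and each given the same weight in both libraries. Chil3 was then at log2 -1.75 against -3.25 unweighted, Cxcl13 at 1.67 against 2.52 and Apoc1 at 1.38 against 2.43. LPM-like clusters with few cells of 1 library, such as that led by Cirbp (5 female and 382 male cells), were left out of both values. The unweighted values are therefore not the main ratios. The main sums rested on 3622 female cells with 35510287 UMIs and 2216 male cells with 24933524 UMIs.

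The other genes among the 12 with the largest female ratios were Mrvi1 (3.97-fold), Tln2, a talin that links integrins to actin (3.44-fold), Fscn1, which bundles actin (3.38-fold), Lst1 (2.98-fold), the scavenger receptor Colec12 (2.76-fold) and Asz1, a gene known from germ cells (2.51-fold). Among the 12 with the largest male ratios, 8 belong to the cell cycle. They were the mitotic cyclin Ccnb2 (5.47-fold, log2 -2.45, -2.69 to -2.22), the histones Hist1h2ae (4.11-fold) and Hist1h1b (3.28-fold), 2810417H13Rik, a PCNA-binding factor (3.81-fold), Cenpf (3.53-fold), Tk1, a thymidine kinase (3.45-fold), Birc5 (3.43-fold) and Mki67, the proliferation marker (3.26-fold). The remaining male genes were Emp1 (3.42-fold), a membrane protein, and Vim, the intermediate filament vimentin, at 653.5 against 196.3 CPM (3.33-fold, log2 -1.74, -1.78 to -1.69). With the same weight per cluster in both libraries, Vim, Fscn1 and Asz1 were at log2 -1.06, 0.72 and 0.28, against -1.73, 1.57 and 1.17 unweighted, and Arg1 and Emp1 at -1.89 and -1.24. The 8 cell-cycle genes all fell below 2-fold and 4 of them turned, with log2 from -0.66 (Hist1h2ae) to 0.23 (Cenpf), against -2.65 to -1.93 unweighted.

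On mm10, Cxcl13 lies on chromosome 5 from 95956951 to 95961068, Saa3 on chromosome 7 from 46711998 to 46715700 and Cd209b on chromosome 8 from 3917655 to 3926844. Apoc1 lies on chromosome 7 from 19689481 to 19692660, next to Apoe at 19696109 to 19699188. Chil3 lies on chromosome 3 from 106147554 to 106167564, Arg1 on chromosome 10 from 24915221 to 24927484 and Vim on chromosome 2 from 13573927 to 13582826. All 7 of these and Apoe are annotated as protein-coding. The symbol 2810417H13Rik had no match in the annotation.

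In all, 4492 genes reached 20 CPM in either library, of which 20 were at least 2-fold higher in the female and 56 in the male library, so 26.3% of these genes were higher in the female library. The median log2 ratio of all 4492 genes was -0.13, and TMM scaling, which brought it to -0.00, gave 28 genes higher in the female and 36 in the male library, or 43.75% female. All 24 genes named above stayed at least 2-fold apart the same way with TMM. Without cycling cells, 16 genes were higher in the female and 28 in the male library, and Hist1h2ae, Mki67 and Hist1h1b fell below 2-fold with log2 ratios of -0.88, -0.77 and -0.65. The libraries hardly shared LPM-like clusters: clusters 1, 2, 3, 5, 7 and 10 held mostly female cells (898 female and 15 male cells in cluster 1), and clusters 0, 6 and 8 mostly male cells (21 female and 1176 male cells in cluster 0). The cycling clusters 12, 14 and 16 and cluster 15 held cells of both libraries.

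**Figure D2:**
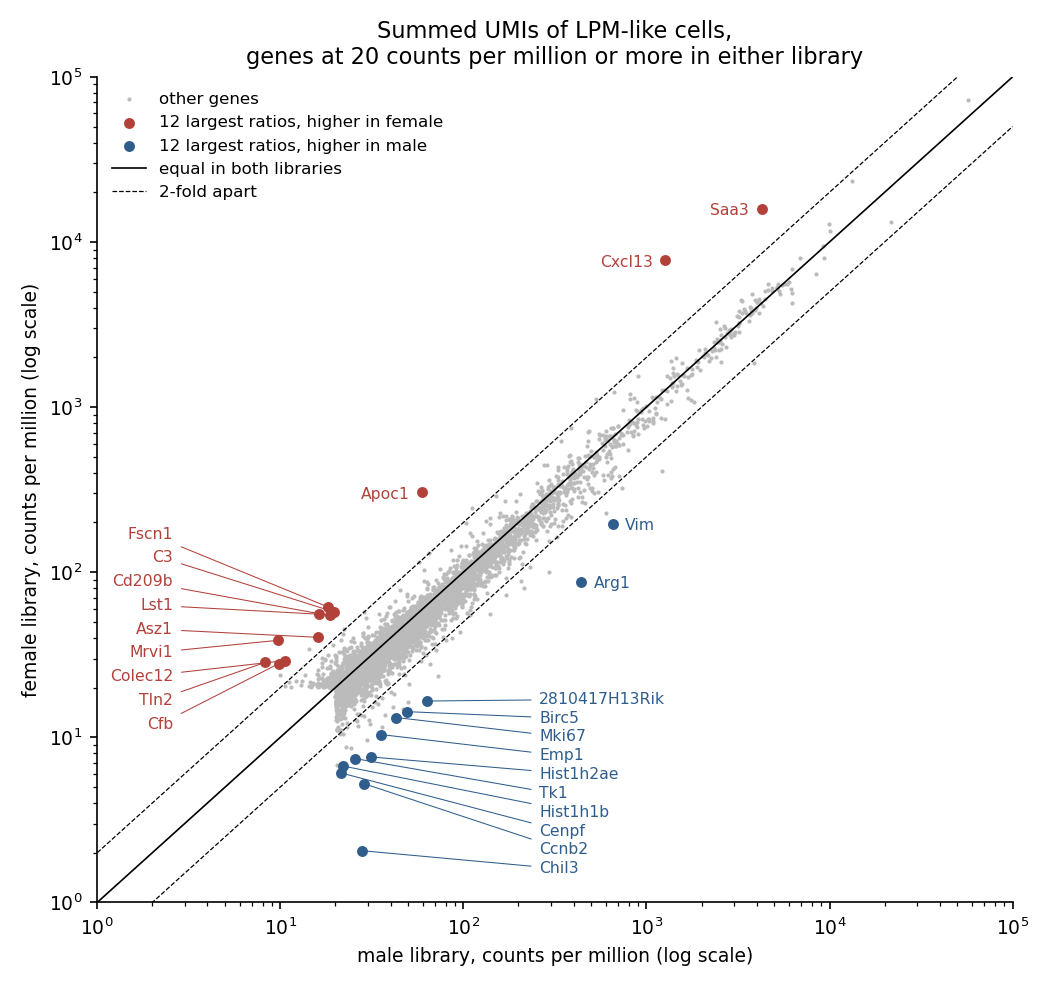
CPM in the male (x axis) and the female library (y axis), both on log scales, for summed UMIs of LPM-like cells. Each point is 1 gene at 20 CPM or more in either library without the sex check genes, coloured points are the 12 genes with the largest ratio each way, the solid line marks equal levels and dashed lines a 2-fold difference. Cxcl13 and Saa3 stand out among abundant genes above the line, at 7724 and 15883 CPM in the female library.

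Genes linked to long residence in the cavity were higher in female LPM-like cells. Here and in every list below, a member was counted as higher only at 1.5-fold or more. Of the 10 measured members of that list, 6 were at least 1.5-fold higher in the female library, 0 in the male library and 4 lay between, with a median log2 ratio of 0.75, at percentile 100 of the random lists. Percentiles were nearly as high for lists with smaller medians, such as 99.69 for complement, 99.87 for chemokines and cytokines, 99.96 for the GATA6 and retinoid list and 99.85 for glucocorticoid response. Besides Cxcl13, Cd209b and Colec12 they were Timd4, a receptor for dying cells, at 445.4 against 276.1 CPM (log2 0.69, 0.65 to 0.73), Apoe, a lipid carrier, at 23323 against 13312 CPM (log2 0.81, 0.80 to 0.81), and the complement gene C4b (log2 0.89, 0.86 to 0.91). Vsig4 and Folr2 lay between at log2 0.39 and 0.35, and Cd5l at -0.26. Folr2 was at 0.98 with clusters made without 2-fold genes, and the median of the list fell to 0.39 with every member with 10 UMIs in all.

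Interferon response genes were also higher in female LPM-like cells. Of 18 measured members, 9 were at least 1.5-fold higher in the female library, 0 in the male library and 9 lay between, with a median of 0.59 at percentile 100. This median stayed at 1.5-fold or more in 7 of 22 alternatives and was 0.46 at the lowest. The examples with the largest ratios were Oas2 (log2 1.28, 1.01 to 1.56) and Oasl2 (log2 1.27, 1.10 to 1.44), both of the oligoadenylate synthetase family, Usp18 (log2 1.23, 0.90 to 1.58) and Ifi27l2a at 1112 against 527.6 CPM (log2 1.08, 1.05 to 1.10). MHC class I genes lay slightly to the female side, with 0 of 10 members 1.5-fold apart and a median of 0.20 at percentile 99.96 (B2m log2 0.41, 0.39 to 0.42). Of 5 measured X-linked genes known to escape inactivation, the median was 0.37 and Kdm6a alone was at least 1.5-fold apart (2.06-fold higher in the female library, log2 1.05, 0.81 to 1.29). Kdm5c, Eif2s3x and Ddx3x were at log2 0.44, 0.37 and 0.33, and Pbdc1 lay on the male side at -0.22 (-0.35 to -0.10).

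Cell cycle genes were higher in male LPM-like cells. All 23 measured genes of the G2M list were at least 1.5-fold higher in the male library, with a median of -1.78 (Ccnb1 log2 -2.24, -2.64 to -1.86; Plk1 -2.18, -2.68 to -1.71). In the S phase list 17 of 18 were at least 1.5-fold higher in the male library and 1 lay between, with a median of -1.20 (Rrm2, a subunit of ribonucleotide reductase, log2 -2.16, -2.44 to -1.88). With cycling cells left out, the S phase median was -0.63 and the G2M median 0.30, and Ccnb1, Plk1 and Rrm2 were at -1.13, -0.96 and -1.49. All named G2M genes, which had been chosen for their large ratios, stayed on the male side there, from -2.11 (Ccnb2) to -0.77 (Mki67). The G2M median covers only members still at 5 CPM, whose number is not given here.

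MHC class II genes were higher in male LPM-like cells, with 4 of 6 members at least 1.5-fold higher, 2 between and a median of -0.69. H2-Aa was at 112.1 against 65.2 CPM (log2 -0.78, -0.86 to -0.70) and its chaperone Cd74 at 371.9 against 223.5 CPM (log2 -0.73, -0.78 to -0.69). These genes are abundant in the dendritic and MHCII macrophage-like cells, with H2-Aa at 18501 CPM in male cDC2-like cells. The median was under 1.5-fold in 11 of 22 alternatives, at -0.36 with cycling cells left out and also with clusters made without 2-fold genes, and at -0.25 without cells over 2 times the median UMIs. In cells chosen by single UMIs and without a UMI of Ccr2, it was -0.13 and Cd74 was at 0.01. Of 7 measured genes of recent monocyte origin, 3 were higher in the male library, 1 in the female library and 3 lay between, with a median of -0.18. They were Chil3, the chemokine receptor Ccr2 (log2 -2.18, -2.46 to -1.91) and Retnla, a resistin-like protein, at 1215 against 411.8 CPM (log2 -1.56, -1.59 to -1.53), while the mannose receptor Mrc1 was higher in the female library (log2 0.67, 0.37 to 0.96). In the cells chosen by single UMIs, Retnla was at log2 -0.78 and Mrc1 at 1.36, and the median of this list went to 0.14, while with a floor of 20 CPM it was -0.87. With clusters made without 2-fold genes, Mrc1 was at 1.42. Ccr2 moved by over 1.5 times in 6 of 19 alternatives, to -0.95 (1.94-fold) with all cells kept. Of 17 glycolysis and hypoxia genes, 5 were higher in the male library and 12 lay between, with a median of -0.26. Among them were Pkm and Gapdh, at log2 -0.78 (-0.82 to -0.74) and -0.76 (-0.78 to -0.74).

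Of the next lists, all but complement had members on both sides. In the complement list, 4 of 12 members were at least 1.5-fold higher in the female library and 0 in the male library, with a median of 0.14. They were C3, Cfb, C4b and Cd55, an inhibitor of complement activation (log2 2.73, 2.25 to 3.25), while C1qa was at 0.00. Of 17 measured C-type lectins and scavenger receptors, 5 were higher in the female library, 4 in the male library and 8 lay between, with a median of -0.22. Stab1, a scavenger receptor, was at log2 0.84 (0.72 to 0.97) and Clec1b at -1.18 (-1.50 to -0.86). Of 22 lipid and cholesterol genes, 2 were higher in the female library, Apoe and Apoc1, 4 in the male library and 16 lay between, with a median of -0.13. The fatty acid carrier Fabp5 was at -0.76 (-0.79 to -0.73). In the GATA6 and retinoid list, 2 of 16 were higher in the female library, 1 in the male library and 13 lay between, with a median of 0.14. Tgm2, a transglutaminase, was at 1.41 (0.98 to 1.85), Ltbp1 at 0.65 (0.61 to 0.69), and Arg1 was the male gene. Of 10 glucocorticoid response genes, Per1 (log2 1.56, 1.15 to 2.00) and Tsc22d3 (1.01, 0.92 to 1.09) were higher in the female library, Anxa1 (-0.91, -0.97 to -0.86) in the male library and 7 lay between, with a median of 0.17.

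The members of the remaining lists lay mostly between. Toll-like receptor sensing had a median of -0.00 and 1 of 13 members higher in the female library, Tlr8 (log2 0.77, 0.42 to 1.13). Chemokines and cytokines had a median of 0.14 and 2 of 14 higher in the female library, Cxcl13 and Cxcl12 (57.5 against 28.7 CPM, log2 interval 0.88 to 1.13). Lysosome and phagocytosis had a median of -0.06 and 2 of 26 higher in the female library, Timd4 and Stab1. Adhesion and coagulation had a median of -0.11 and 1 of 20 higher in the male library, Cd44, a hyaluronan receptor (log2 -0.86, -0.93 to -0.78). Dissociation and immediate early genes had a median of -0.05 and 1 of 19 higher in the male library, Klf4 (log2 -0.99, -1.10 to -0.88). Steroid and nuclear hormone receptors had a median of -0.06 and 0 of 5 measured members 1.5-fold apart, with Ppard at -0.26 and Ncoa7 at 0.18. Only these 5 of the 15 genes in the list reached 5 CPM, among them also Thra and Nr1h2. Most of the sex steroid receptor genes Esr1, Esr2, Ar and Pgr were therefore not measured, and the median says little on them. Nuclear oxidative phosphorylation had a median of -0.21 and 3 of 19 at least 1.5-fold higher in the male library (17 of 19 by sign alone), among them Atp5b (log2 -0.77, -0.82 to -0.73). Mitochondrially encoded genes had a median of -0.22 and 2 of 13 at least 1.5-fold higher in the male library (12 of 13 by sign alone), mt-Nd3 (log2 -0.83, -0.87 to -0.79) and mt-Atp8 (-0.69, -0.79 to -0.59). Nuclear retained RNA had a median of 0.21 and 0 of 4 members 1.5-fold apart, with Malat1 at 0.37. Of the list of RNA from other cells, S100a8 alone reached 5 CPM, at 22.1 CPM in male and 13.6 CPM in female cells (log2 -0.71, -0.89 to -0.53). With TMM the medians for Toll-like receptor sensing, lysosome, adhesion, immediate early genes and nuclear receptors lay on the female side, at 0.12, 0.07, 0.02, 0.08 and 0.07. Those for nuclear oxidative phosphorylation and mitochondrially encoded genes were -0.087 and -0.094 with TMM. The median of all genes was -0.13 without it, so counts by sign alone lean to the male side.

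**Figure D3:**
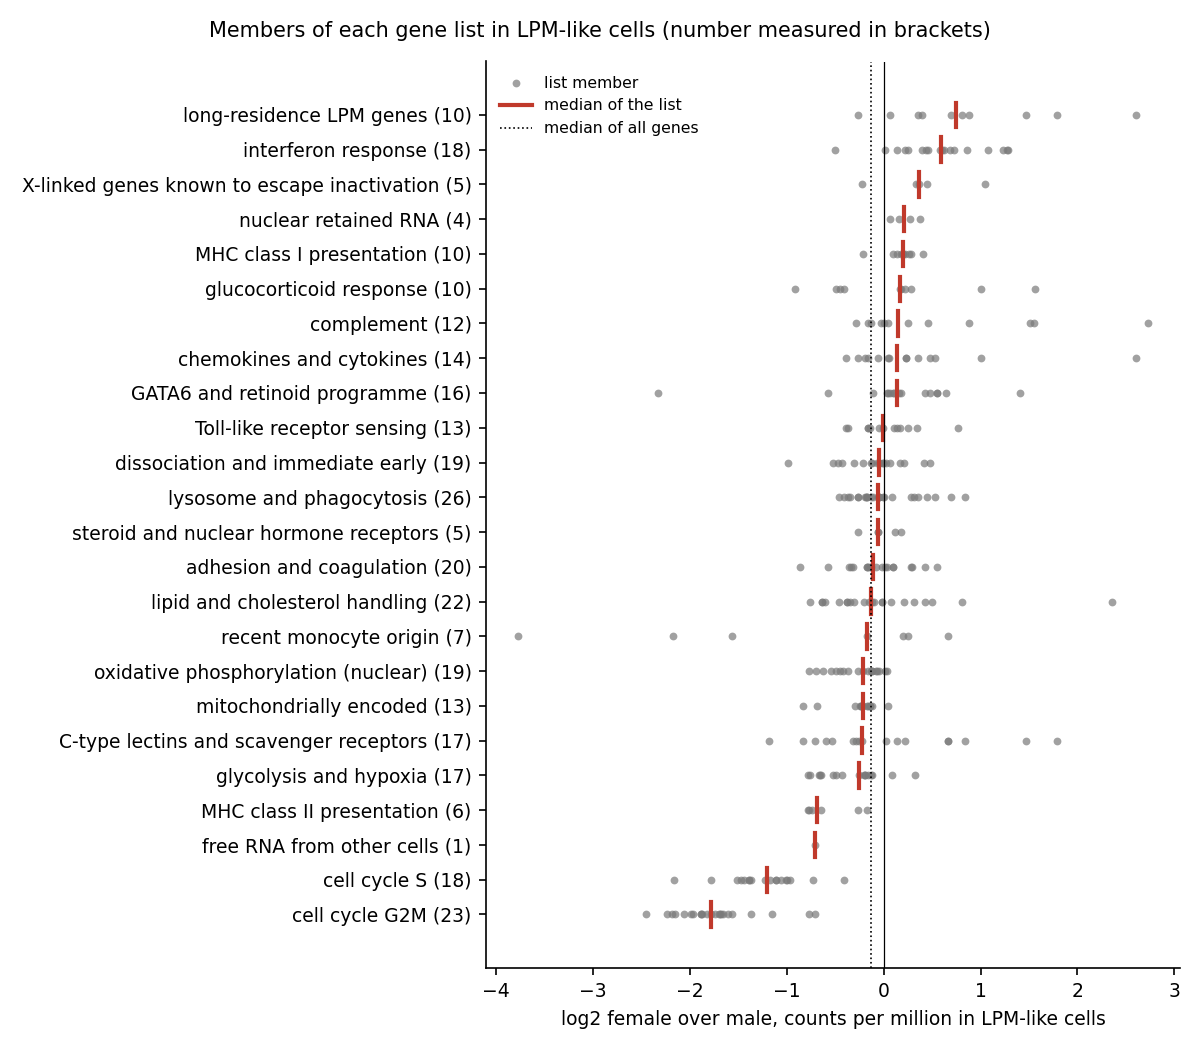
Log2 female over male ratio of CPM in LPM-like cells (x axis) for each measured member (grey points) of each gene list (y axis, number of members in brackets), with the list's median as a red bar. The dotted line marks the median of all genes at -0.13; the long-residence and interferon lists lie farthest to the female side, at 0.75 and 0.59, and the G2M and S lists farthest to the male side, at -1.78 and -1.20.

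The subset panel asked how many LPM-like cells held RNA of genes that mark macrophage subsets. After thinning, with 362 female and 201 male shallower cells left out, Timd4 was found in 79.4% of 3260 female cells (77.9 to 80.7) and in 55.9% of 2015 male cells (53.7 to 58.1). Cxcl13 was found in 99.5% of female (99.2 to 99.7) and 62.9% of male cells (60.8 to 65.0), Cd209b in 21.7% (20.3 to 23.1) and 7.34% (6.24 to 8.57), and Vsig4, a complement receptor, in 49.4% (47.6 to 51.1) and 34.3% (32.2 to 36.4). The adhesion molecule Selp was in 81.8% of female (80.5 to 83.2) and 76.0% of male cells (74.1 to 77.8), and the folate receptor Folr2 in 9.69% (8.70 to 10.8) and 6.95% (5.88 to 8.15). Unthinned shares in female and male cells were 84.4% and 66.0% for Timd4, 99.9% and 73.5% for Cxcl13, 27.3% and 11.2% for Cd209b, 56.9% and 42.8% for Vsig4, 90.8% and 89.4% for Selp and 14.4% and 10.4% for Folr2.

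The cDC2-like cells, which should lack these genes, gave the background from free RNA. It was 21.4% in female and 16.3% in male cDC2-like cells for Timd4, 85.7% and 20.4% for Cxcl13, 1.79% and 2.04% for Cd209b, 16.1% and 12.2% for Vsig4, 10.7% and 4.08% for Selp and 1.79% and 2.04% for Folr2. In the male library the upper limit of this background, 10.9% for both Cd209b and Folr2, lay above the shares in LPM-like cells. These 2 shares were therefore not told from background at this depth. Their levels lay above it, at 16.2 CPM (Cd209b) and 18.9 CPM (Folr2) in male LPM-like cells against 2.06 CPM each in male cDC2-like cells. In the female library the Folr2 share of 9.69% (8.70 to 10.8) lay barely above the upper limit of its background, 9.55%. Median UMIs were 9679 in female and 10766.5 in male LPM-like cells, against 7606 and 8521 in cDC2-like cells, of which 56 female and 49 male cells were deep enough to thin.

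Some panel genes differed little, or their share did not tell them from background. Icam2 was found in 97.7% of female and 98.3% of male LPM-like cells (28.6% and 34.7% of cDC2-like cells), Prg4 in 100% and 99.9% (58.9% and 53.1%), and Lyve1 in 5.03% and 4.52%, with 0 of 56 and 0 of 49 cDC2-like cells, which allows up to 6.38% and 7.25%. Apoe and Saa3 were in nearly all cells of both classes: Apoe in 100% of both, and Saa3 in 100% and 99.7% of LPM-like and 100% and 95.9% of cDC2-like cells. Cd163 was in 1.84% of female and 2.48% of male LPM-like cells, below its 8.93% and 8.16% in cDC2-like cells. Its level was also lower in LPM-like cells, at 3.38 CPM in female and 4.49 CPM in male cells, against 16.9 and 18.5 CPM in cDC2-like cells. The cDC2-like cells therefore give no background from free RNA for Cd163. Retnla was in 75.2% and 87.4%, within the interval of its 71.4% in female (57.8 to 82.7) and 79.6% in male cDC2-like cells (65.7 to 89.8). Its level lay above that of cDC2-like cells in both libraries, at 411.8 against 192.5 CPM in female and 1215 against 241.1 CPM in male cells. For H2-Aa (29.4% and 32.8%), Ccr2 (1.81% and 6.05%) and Cd226 (0.0614% and 0.0993%) the cDC2-like cells give no background, since they held these genes themselves, at 100% and 100%, 62.5% and 73.5%, and 8.93% and 10.2%. Unthinned shares in female and male LPM-like cells were 97.4% and 98.5% for Icam2, 99.8% and 100% for Prg4, 6.79% and 5.69% for Lyve1, 2.90% and 4.15% for Cd163 and 87.1% and 95.1% for Retnla. They were 41.5% and 49.5% for H2-Aa, 2.98% and 8.44% for Ccr2, 0.0828% and 0.181% for Cd226, and 100% in both for Apoe and Saa3.

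**Figure D4:**
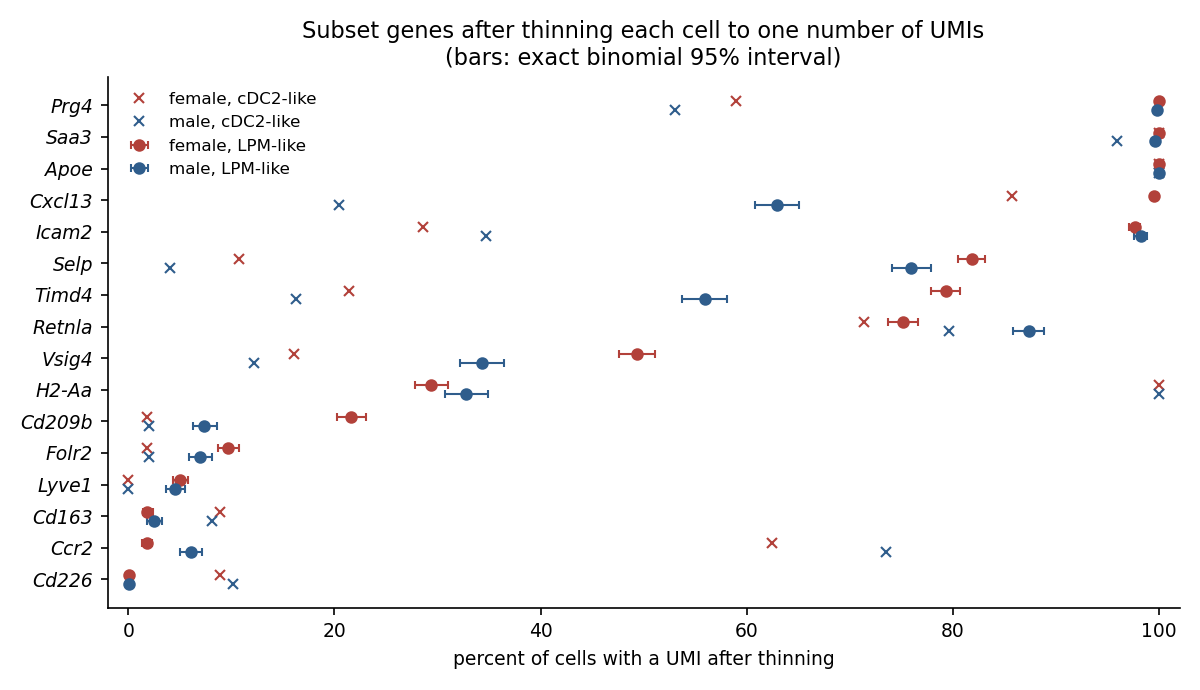
Percent of cells with a UMI of each subset gene (x axis, genes on the y axis) after thinning every cell to 5817 UMIs, in LPM-like cells (dots, exact binomial 95% intervals as bars) and cDC2-like cells (crosses) of each library. Timd4, Cxcl13, Cd209b and Vsig4 lie further right in the female library, at 79.4%, 99.5%, 21.7% and 49.4% against 55.9%, 62.9%, 7.34% and 34.3%.

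More male than female LPM-like cells were in the cell cycle by the count of G2M genes. UMIs of at least 3 G2M genes were found in 161 of 2015 male cells, or 7.99% (6.84 to 9.26), and in 81 of 3260 female cells, or 2.48% (1.98 to 3.08). The summed level of the list was 504.9 CPM in male and 172.7 CPM in female LPM-like cells. Unthinned shares were 12.2% in male and 3.51% in female cells. No cDC2-like cell met the rule, with 0 of 49 male and 0 of 56 female cells, which allows up to 7.25% and 6.38%.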

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

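The search for genes that went opposite ways in different cell classes was first run on the 24 genes with the largest ratios, where it found none, and was widened to the subset panel only after the values of Retnla had been seen. Retnla stood out because its direction differed between classes. In MHCII macrophage-like cells it was 2.13-fold higher in the female library (2.07 to 2.19), at 20231 against 9493 CPM, and in LPM-like cells it was 2.95-fold higher in the male library, at 1215 against 411.8 CPM. The LPM-like ratio depended on which cells were taken, with log2 -0.78 in cells chosen by single UMIs against -1.56. The difference between the classes was not tested, and the MHCII macrophage-like values came from 89 female and 67 male cells.

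B cell RNA stood out because the sort was against CD19 and these cells were in no comparison. Cluster 17 met no naming rule and was mixed, with the dendritic cell genes Ccl17, Cd209a and Mgl2 also among its leading genes. In its 33 female and 13 male cells the B cell receptor gene Cd79a was at 221.6 CPM in female cells (178.4 to 272.1) and 103.3 CPM in male cells (64.0 to 158.0). Ms4a1, which encodes CD20, was at 165.6 CPM in female and 44.3 CPM in male cells of this cluster. With clusters made without 2-fold genes only 12 female and 4 male cells were B cell-like, so these levels rest on a mixed cluster. In LPM-like cells Cd79a was at 1.55 CPM in the female and 1.32 CPM in the male library.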

How the results depend on the processing

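The following were chosen after the data had been seen: leaving out cells over 2 times the median UMIs, leaving out or adding single clusters, and the use of the other clusterings for genes, lists and cycling cells. The count of lists 1.5-fold apart was also added then, and a gene at least 1.5-fold apart was then also required to have an interval that excludes equality before it could count as turned, which left out Cd226 (6 male UMIs), at log2 0.37 without 2-fold genes against -0.77. No leave-one-out or paired analysis was possible because each sex had 1 library and no test was run. Depth limited the smaller classes most, where 3 counts stood for 6.34 CPM in female cDC2-like cells, against 0.0845 CPM in female LPM-like cells. The direction of all 24 genes with the largest ratios held in every scaling and choice of cells that was run, and all 24 stayed at least 2-fold apart except with cycling cells left out (21 of 24). With the same weight per cluster in both libraries, run apart from these, Cenpf, Hist1h1b, Tk1 and Mki67 turned, to 0.23, 0.19, 0.15 and 0.04, and 6 others fell below 2-fold. The Xist and Eif2s3y levels stayed within their intervals in each alternative run for them. Of the alternative log2 ratios of single named genes, 1861 stayed within their interval, 437 moved and 1 turned, with no value for Ccr2 in cells gated on UMIs, which hold none of it; of list medians, 425 moved by less than 0.1, 101 moved by more and 2 turned, where only a median at least 1.5-fold apart could count as turned. By sign alone, 12 values of 7 genes and 26 of 10 lists lay on the other side, among them Cd163 at 0.12 in cells gated on UMIs. Of panel shares, 129 stayed within their interval and 63 moved. The female and male order of panel shares held in all 6 alternatives except for Icam2 (5 of 6), Saa3 (5 of 6) and Prg4 (3 of 6).

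The number of genes at least 2-fold higher in the male library was 36 with TMM, 36 with median of ratios and 28 with cycling cells left out. With a floor of 5 CPM, 47 genes were higher in the female and 175 in the male library. With a floor of 100 CPM these were 7 and 12, and with no floor beyond 10 UMIs in all they were 278 and 653, since the floor sets how many genes count. The log2 ratio of Cd74 turned to 0.00928 in cells gated on UMIs, and the cause was not tested. The median of the G2M list turned to 0.30 with cycling cells left out, which removes the cells chosen by that list. Its named members stayed on the male side there, from -2.11 (Ccnb2) to -0.77 (Mki67). How many members still reached 5 CPM is not given here, so 0.30 does not show that the list as a whole turned. The median of the list of free RNA from other cells turned to 0.49 with every member with 10 UMIs in all, since the main value rested on 1 gene.

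Of the lists with a median at least 1.5-fold apart, 2 were higher in the female and 4 in the male library. The male number was 2 with TMM, with cycling cells left out and with every member with 10 UMIs in all. Of the 4 male lists, MHC class II presentation was under 1.5-fold in 11 of 22 alternatives. Another of the 4, the list of free RNA from other cells, rested on S100a8 alone. The female number was 1 in 14 alternatives, since the interferon list at 0.59 lay at the threshold: the total without mitochondrial, ribosomal protein and sex check genes, mean over cells, all cells kept, cells gated on UMIs, cycling cells left out, cells thinned, at least 1000 genes and at most 5% mitochondrial, resolution 2, clustered without genes that differ 2-fold between libraries, cells over 2 times the library's median UMIs left out, 2 unnamed clusters added, Cirbp cluster left out, Cxcl2 cluster left out and floor of 20. It was 0 with every member with 10 UMIs in all.

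The LPM-like share of female cells was 80.8% with doublets kept, 81.8% with at least 200 genes and at most 20% mitochondrial UMIs, 89.0% with at least 1000 genes and at most 5%, 91.1% at resolution 2, 89.8% without 2-fold genes, 79.5% with each library clustered on its own and 91.9% without cells over 2 times the median UMIs. The unnamed share of female cells was 15.5%, 15.1%, 7.58%, 5.95%, 6.48%, 16.7% and 4.99% in the same order. In male cells the LPM-like share was 88.8% at resolution 2, 84.2% with each library on its own and 88.1% without cells over 2 times the median UMIs. The unnamed share of male cells was 6.85% at resolution 2, 7.67% without 2-fold genes, 13.4% with each library on its own and 6.97% without cells over 2 times the median UMIs. MHCII macrophage-like cells were 1.31% of female and 1.99% of male cells at resolution 2, and 3.48% and 0% with each library on its own, where cDC2-like cells were 0% of female cells. The cause of these moves in class shares was not tested.

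The cycling share of female and male LPM-like cells was 5.31% and 13.7% with 2 genes, 1.96% and 5.96% with 5 genes and 3.51% and 12.2% with no thinning, since each changes the rule itself. Without cells over 2 times the median UMIs the male share was 6.71%, and the cause was not tested.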

Other observations

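The tests of scaling, free RNA (first run as 1 sum over all 12 genes), depth, doublets, aggregates and clustering genes, and the values without the Cirbp cluster were chosen only after the result was seen; the test of the 12 genes with the same weight per cluster was written before. Cells with inflammatory RNA formed a small part of the LPM-like cells of both libraries: with clusters made without 2-fold genes, the cluster led by the chemokine Cxcl2 and the cytokines Tnf and Il6 held 2.42% of female (1.98 to 2.92) and 1.44% of male cells (1.02 to 1.98). A macrophage cluster led by Folr2, the lectin Cd209f, Lyve1 and Cd163, which met no naming rule, held 4.77% of female (4.16 to 5.45) and 3.62% of male cells (2.93 to 4.42) in that clustering, but 11.2% and 1.44% in the main one, so its size was not compared. B cell-like cells numbered 12 in the female and 4 in the male library. A cluster led by Cirbp, a cold-inducible RNA-binding protein, held 5 female and 382 male cells. Cirbp was also higher in the male library in LPM-like cells outside the matching cluster of the main clustering (43.9 against 36.9 CPM), in MHCII macrophage-like cells (51.4 against 19.9 CPM) and in cDC2-like cells (96.8 against 31.7 CPM). Without that cluster, 23 genes were at least 2-fold higher in the female and 69 in the male LPM-like cells.

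The 89 female and 67 male MHCII macrophage-like cells were too few for the comparison of genes, and some of their levels are given as values. Cxcl13 was at 1096 CPM in female (1025 to 1171) and 45.5 CPM in male cells (30.9 to 64.6), Saa3 at 4288 and 457.9 CPM and Apoe at 10730.0 and 4673 CPM. Arg1 was at 102.7 CPM in male (80.1 to 129.8) and 3.73 CPM in female cells (0.769 to 10.9), from 3 UMIs in the female library, and Vim at 1416 and 681.0 CPM. In cDC2-like cells, which give the background from free RNA, Cxcl13 was at 319.4 CPM in female and 49.4 CPM in male cells (31.7 to 73.6), and Saa3 at 1933 and 440.9 CPM (383.8 to 504.1 in male cells). The male levels of Cxcl13 and Saa3 in MHCII macrophage-like cells were therefore not told from background.

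For the 12 genes with the largest female ratios in LPM-like cells, the tables argue against scaling and the mix of clusters as accounts of the whole set: over 4 other scalings the lowest log2 ratio was 1.29 (Cfb, mean over cells), and with each of 9 clusters made without 2-fold genes given the same weight in both libraries the median was 1.42 against 1.78 unweighted. Single genes moved further, Fscn1 and Asz1 to 0.72 and 0.28 from 1.57 and 1.17, Cxcl13 to 1.67 from 2.52 and Apoc1 to 1.38 from 2.43. The mix therefore stays open as part of their ratios. The 9 clusters left out LPM-like clusters with few cells of 1 library. Many of the 9 were still uneven, with 1020 female and 41 male cells in that led by Apoc4, and 44 and 1279 in that led by Arg1. The weighted values thus rest on few cells of 1 library in such clusters. Free RNA would carry the excess to every droplet, but in cDC2-like cells it was at most 12.8% of that in LPM-like cells for Cxcl13, Saa3 and Apoc1 (highest upper limit 17.8%), and 9.45% for the sum of the 8 genes under 100 CPM without Lst1 (upper limit 25.4%), most of which had too few UMIs to judge singly. For Lst1 free RNA stays open, since the value was 74.2% and cDC2-like cells held more of it than LPM-like cells (175.5 against 55.3 CPM in the female library). Sex stays open as an untested biological explanation, and so does any difference in how the 2 libraries were made.

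For the larger share of male LPM-like cells with G2M genes, the tables argue against depth as the whole cause. The male over female ratio was 3.22 after thinning to 1 number of UMIs. It was 3.26 without cells over 2 times the median UMIs (6.71% against 2.06%). That choice keeps doublets with fewer UMIs, so it cannot exclude doublets. If all G2M UMIs of the male library were free RNA spread over all droplets, 33.9% of male cells would hold 3 G2M genes, against 7.99% found. The bound first written for this test ran the wrong way and was replaced after the value was known. Spreading the same UMIs raises the share of cells with 3 genes, so any concentration in some cells gives a lower share. The value therefore shows only that these UMIs were not all spread at random. Whether free RNA added to the difference between the libraries stays open. With the same weight per cluster, the 8 cell-cycle genes had log2 ratios from -0.66 (Hist1h2ae) and -0.65 (Ccnb2) to 0.23 (Cenpf), against -2.65 to -1.93 unweighted. This changed the weight of all 9 clusters at once and left out a cycling cluster led by Ccnb2 (12 female and 30 male cells). Cycling clusters are also themselves marked by such genes. How much of the excess lay in the size of the cycling clusters was therefore not settled. Sex and the making of the libraries stay open and untested.

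Cluster 9, between LPM-like and MHCII macrophage-like cells in its markers, held 1.08% of female (0.798 to 1.44) and 6.93% of male cells (5.98 to 7.98), with median UMIs of 13861 and 15753.5. The tables argue against clusters drawn by the 2-fold genes as the whole cause, since without those genes the male share was 4.05% (3.32 to 4.88) and the female share 1.71% (1.34 to 2.14), but the size of the difference depended on the clustering. The male share was higher in all 8 alternatives, with intervals that overlapped in 2: 3.09% (2.44 to 3.86) against 2.103% (1.69 to 2.58) with at least 1000 genes, and 2.15% (1.61 to 2.80) against 1.25% (0.940 to 1.64) without cells over 2 times the median UMIs. Random pairs of both classes would make up 4.50% of male droplets if every droplet held a pair, below the male lower limit of 5.98%. Without 2-fold genes such pairs would make up 4.62%, above the share of 4.05% (3.32 to 4.88). Both values took the class shares from clusters that leave out the cells in question. If those cells were pairs, the class shares and the values would be higher, so the values cannot exclude chance pairs. The part of droplets with 2 cells was not measured either, and chance doublets stay open. Aggregates cannot be told apart from a state between the classes, since 1 gene lay 2-fold above both in the male library, Folr2 at 122.2 CPM against 18.9 and 54.3 CPM; sex stays open and untested.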
